A study of Homo sapiens with 284 samples.

How the data were processed

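The series holds RNA-seq of cultured human smooth muscle cells from the ascending aorta, in 145 libraries of cells grown with 5% fetal bovine serum (FBS), called proliferative, and 139 libraries of cells kept without FBS for 24 hours, called quiescent. Groups and donor numbers were taken from the library titles and the treatment label. Of 148 donor numbers, 136 occur in both groups, 9 only in the proliferative group and 3 only in the quiescent group.

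Per the labels' protocols, RNA was isolated with RNeasy Mini columns and DNase digestion, and libraries were made with the Illumina TruSeq Stranded mRNA kit. Per the submitters' processing notes, Trim Galore and STAR were used with the genome build hg38 (GRCh38), with no versions. The program that turned alignments into gene values, its use of strand, and its annotation release are not given in the sources used here, so reads of genes that overlap on opposite strands may not have been told apart. The deposited values, one table per group, are TPM, transcript abundances scaled to a fixed total: each column sums to 1000000 over 58319 features, of which 92 are ERCC spike-in sequences and 58227 carry Ensembl gene identifiers. The authors' TPM values were used as deposited, apart from leaving out the spike-in features without rescaling the rest. Each column was matched to its library by the name in the header. No column was left unmapped, and no 2 columns were identical.

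Symbols for 58212 identifiers came from the reference gene tables. Gene types and chromosomes were taken from GENCODE 29 by identifier, and positions only for the 39509 identifiers found there with the same version. For other genes the chromosome alone is given, where known. No further normalisation was applied for the primary test. A gene was tested if at least 20% of all libraries had at least 0.1 TPM, which left 21089 genes, 13844 of them annotated as protein-coding. Values were analysed as log2(TPM + 1), so a fold change is on the log2(TPM + 1) scale and understates the change of genes with low values.

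The design fixed beforehand assumed read counts. As the tables hold TPM, the planned test of counts was replaced by limma with a mean-variance trend, applied to all 284 libraries with the condition as the only term, and planned settings that need counts were not run. Fold changes are quiescent over proliferative. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over the 21089 genes, two-sided, with a threshold of 0.05. A count of genes with at least a 2-fold change has also a log2 fold change of at least 1 in size. Beside this, the counts were recomputed with median-ratio factors, upper quartile factors, no filter, a filter of at least 1 TPM in at least 50% of libraries, a pseudocount of 0.1, a test against a 1.5-fold change, the paired donors without a block, odd or even donor numbers, and the donor number as a block over paired donors. Settings added after seeing the data were TPM rescaled to the sum of nuclear protein-coding genes, 5 residual components as covariates, robust regression, and fits without donors in doubt or without libraries high in endothelial markers.

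A set of 40 gene lists was fixed beforehand, of which 39 had at least 5 tested members. They cover the cell cycle (DNA replication, mitosis, replication-dependent histones, cell cycle inhibitors and quiescence genes), the smooth muscle state (contractile genes, genes of modulated smooth muscle, fibrillar matrix, matrix proteases, osteochondrogenic genes, Notch targets), serum and growth signalling (immediate early genes, YAP and TEAD targets, TGF-beta targets, FOXO targets, glucocorticoid targets, circadian clock genes, metallothioneins), metabolism (cholesterol synthesis, fatty acid synthesis, LXR targets, autophagy and lysosome, ATF4 and amino acid genes, ER chaperones and stress, ribosome biogenesis, ribosomal proteins, nuclear and mitochondrially encoded oxidative phosphorylation, glycolysis and hypoxia), stress and immunity (p53 targets, interferon response, NF-kB inflammatory genes, complement), genes near coronary artery disease loci, and markers of endothelial cells, leukocytes, adventitial fibroblasts, pericytes, epithelial and mesothelial cells, neural and Schwann cells, and cardiomyocytes. The lists were compared with all other genes by limma's camera test with a preset inter-gene correlation of 0.01, again with an estimated correlation, by ranks, and with the donor block, with Benjamini-Hochberg adjustment over the 39 lists.

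Named genes follow a rule fixed beforehand. It takes the 12 largest rises and the 12 largest falls among genes past the threshold with a mean log2(TPM + 1) of at least 2 and the same direction in at least 90% of paired donors. It adds, per list, the 4 members past the threshold with the largest change, 10 contractile and cycle genes named in advance, the 10 genes with the highest correlation between conditions, and the 5 genes with the largest rise and the 5 with the largest fall in spread. A few genes that this rule takes are not reported here.

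Across the 136 paired donors, each gene's proliferative and quiescent values were correlated (Pearson, with Spearman as alternative) and compared with 20 shuffles of the donor numbers. Spread between donors was compared between conditions by the Pitman-Morgan test for paired variances, and again with a pseudocount of 0.1, added after seeing the data. Mean z scores of the mitosis and of the contractile genes, taken within each condition, were correlated across libraries. Across paired donors, z scores of the changes were used. Permutation tests had 100000 resamples, whose smallest possible p is 1e-05. The gene tests were also repeated on 100 splits of the libraries, the real one included, and with the donor block on 100 in which conditions were exchanged within random paired donors, the real one included.

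Donor numbers were checked as pairs. After subtracting each group's means, the libraries of a donor correlated with a median r of 0.833, and 134 of 136 pairs exceeded 0.1. The lowest r was -0.051. No pair was left out for a low value, and donors were not put in doubt by this measure. Over the 1000 most variable genes, the quiescent library of the same number was the closest one for 125 of 136 proliferative libraries, and in the other direction 130 of 136. The numbers are therefore used as pairs, with the series design text speaking of donors in both conditions. In 2 donors the 2 libraries appeared exchanged between conditions, and in 1 donor they were nearly identical (r = 0.997, next highest 0.993), so that it is not known whether they come from separate samples. These 3 donors were kept in the primary test and left out in a repeat.

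TPM values do not give the depth by themselves, but low values fall in steps. Over 9724 genes detected in 3 to 25% of libraries, 89.1% of nonzero values were whole multiples of a step, within a tolerance of 0.05 of a step. Of 3402 single-exon genes among them, 55.8% had a step of 1 read and 31.2% a step of 2 reads for the gene's length, within 1%. From these steps the reads assigned to genes were estimated, in units of 1000000 reads per library, at 105 ± 14.3 (SD, n = 145, range 77.1 to 159) in the proliferative group and 106 ± 16.2 (SD, n = 139, range 77.9 to 166) in the quiescent group. These are estimates, since the counting rule is not given in the sources used here. No batch or date was found in the labels or the tables, so values within batches could not be given.

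The scripts were tested on simulated data before use. The condition effect was removed from the real values, labels were drawn at random, and 50 genes each with a mean log2(TPM + 1) of at least 1 were given a known change. The fit of 21089 genes called 82% of genes changed by 0.25, 98% changed by 0.5, 98% changed by 1 and 100% changed by -1 on the log2 scale, and 0.0144% of 20889 unchanged genes. Over 2000 simulated genes, the paired variance test called 100% of genes with a 1.5-fold wider SD and 0.389% of unchanged genes. These values were drawn as normal and independent between genes, so the rates may not hold for genes with a tail of extreme libraries. Simulated pairs with a true correlation of 0.5 gave a median r of 0.501. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Levels of genes on the Y chromosome and of the X-inactivation transcript are not reported here.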

Results

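Gene expression was measured by RNA-seq in cultured human smooth muscle cells from the ascending aorta, in 284 libraries. Of these, 51.1% came from cells with 5% FBS (proliferative) and 48.9% from cells without FBS for 24 hours (quiescent), and 91.9% of the donor numbers were present in both groups. Means of expression are over all libraries of a group, so n is the full size of that group throughout. Expression is given as TPM with the SD between libraries, and changes as log2 fold changes of log2(TPM + 1), quiescent over proliferative, with their SE. Unless said otherwise, SE and adjusted p are from the fit without the donor block, which leaves differences between donors in the residual. Genes that vary between donors may therefore not pass there. For DCN the limma adjusted p was 0.0022 without and 1.34e-30 with the block. Reads assigned to genes, estimated from the steps of low TPM values and in units of 1000000, were 105.5 ± 14.3 (SD) in proliferative and 105.6 ± 16.2 (SD) in quiescent libraries. Nuclear protein-coding genes summed to 469820 ± 24990 TPM (SD) in proliferative and 433766 ± 31660 TPM (SD) in quiescent libraries, while the mitochondrial ribosomal RNAs summed to 244812 ± 32136 and 271056 ± 38951 TPM. RN7SL1, the RNA of the signal recognition particle, held 183066 ± 33783 and 194722 ± 40200 TPM.

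The first comparison asked how the transcriptome of aortic smooth muscle cells differs without serum. VCAM1 (ENSG00000162692.12, chromosome 1), an adhesion molecule for leukocytes, rose from 4.91 ± 8.07 TPM (SD) to 24.3 ± 26.95 TPM (SD), a log2 fold change of 2.12 ± 0.16 (SE; limma adjusted p = 1.11e-29), in 94.9% of paired donors. SOD2 (ENSG00000112096.18, chromosome 6), the mitochondrial superoxide dismutase, rose by 1.84 ± 0.16, and INSIG1 (ENSG00000186480.13, chromosome 7), which holds the sterol sensor in the endoplasmic reticulum, by 1.76 ± 0.12. The histone gene H3C2 (ENSG00000286522.1) fell from 403 ± 276 to 67.2 ± 106.6 TPM, with a log2 fold change of -2.79 ± 0.18 (limma adjusted p = 1.43e-38), in 96.3% of paired donors.

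The other large rises under the rule for named genes were FABP3 (1.74 ± 0.13), a fatty acid binding protein, GAS1 (1.62 ± 0.18), which was named for its induction at growth arrest, COL14A1 (1.59 ± 0.24), SLC40A1 (1.59 ± 0.13), the cellular iron exporter, PPL (1.57 ± 0.18), FBXO32 (1.53 ± 0.16), a muscle ubiquitin ligase, TNFAIP2 (1.42 ± 0.12), PDGFRB (1.41 ± 0.15), the receptor for platelet-derived growth factor B, and GPNMB (1.36 ± 0.13). Of the 12 largest falls, 9 were histone genes, with H3C8 (ENSG00000273983.1, GRCh38 chromosome 6, 26269405 to 26271815) at -2.71 ± 0.16 and H1-5 (ENSG00000184357.4, chromosome 6, 27866849 to 27867529) at -2.61 ± 0.16. H2BC14 (-2.69 ± 0.16), H2AC14 (-2.68 ± 0.16), H3C12 (-2.54 ± 0.15), H3C3 (-2.52 ± 0.16), H3C7 (-2.43 ± 0.17) and H2AC16 (-2.39 ± 0.14) were the others. Histone genes of one type are near-identical copies, so reads may have been split between them, and their values are uncertain one by one. The remaining 3 were IL1B (-2.61 ± 0.31, limma adjusted p = 8.20e-15), the cytokine interleukin 1 beta, from 241 ± 606 to 92.2 ± 347 TPM, ANXA10 (-2.57 ± 0.15) and ESM1 (-2.38 ± 0.21).

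Across all genes, 13384 of 21089 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 5785 of them higher and 7599 lower in quiescent libraries, so that 43.2% were higher. Among protein-coding genes it was 9765 of 13844, with 3234 higher and 6531 lower. A change of at least 2-fold was found for 330 genes, 43 higher and 287 lower. Since the sum of protein-coding TPM was lower without serum, the split depended on the scaling: 61.3% of called genes were higher with median-ratio factors (8695 higher, 5494 lower), 65.4% with upper quartile factors (9377 and 4956) and 59.8% with TPM scaled to the protein-coding sum (8316 and 5593), while genes with at least a 2-fold change stayed mostly lower (57 higher and 229 lower, 65 and 215, and 56 and 237). The median log2 fold change of all genes was -0.0074 as deposited and 0.032, 0.042 and 0.029 under these scalings. Over the 330 genes, a median of 94.9% of paired donors moved in the direction of the group difference (range 74.3% to 97.8%). The 330 genes were chosen by the group difference in these same libraries, so a high share is partly fixed by that choice. For the named largest rises and falls a share of at least 90% was required.

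**Figure D1:**
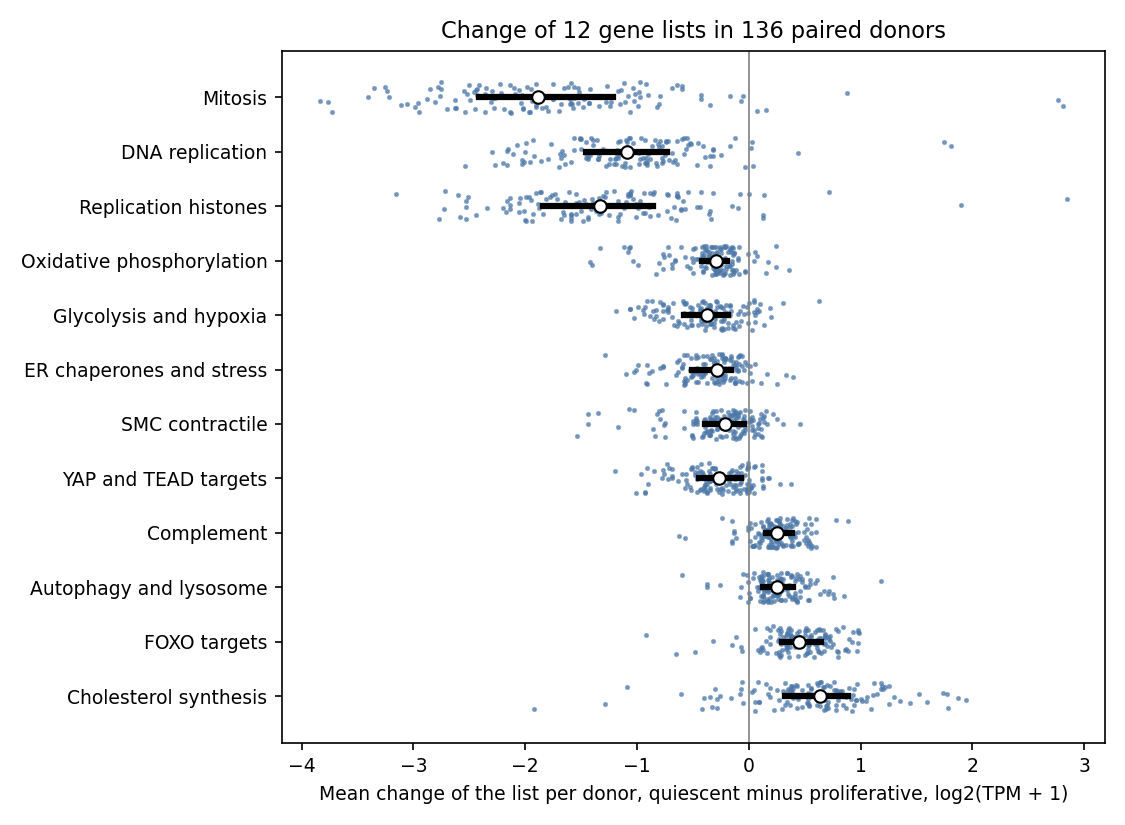
Mean change of each of 12 gene lists per donor, quiescent minus proliferative in log2(TPM + 1), with 1 point per paired donor, the median as a white circle and the middle quartiles as a black bar. The mitosis list was lower in quiescent cells of 96.3% of paired donors and the cholesterol synthesis list higher in 87.5%.

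All 48 measured genes of the mitosis list fell without serum, each by at least 2-fold, with a median log2 fold change of -1.76. They included UBE2C (-2.32 ± 0.13), a ubiquitin-conjugating enzyme of the anaphase-promoting complex, TOP2A (-2.26 ± 0.15), CDK1 (-2.26 ± 0.14), the mitotic kinase, and CDC20 (-2.25 ± 0.13). All 40 genes of DNA replication fell, 20 of them by at least 2-fold, with a median of -0.98, among them CDC45 (-1.94 ± 0.10), RRM2 (-1.90 ± 0.11), DTL (-1.78 ± 0.10) and TK1 (-1.66 ± 0.12). Of 27 replication-dependent histone genes 26 fell and 1 did not pass (median -1.05). The proliferation marker MKI67 fell from 14.5 ± 10.7 to 3.12 ± 4.61 TPM (-1.91 ± 0.13), in 97.1% of paired donors. CCNB1, the mitotic cyclin, changed by -1.76 ± 0.10, MCM2, a subunit of the replicative helicase, by -0.90 ± 0.07 and CCND1 (ENSG00000110092.3, chromosome 11, 69641087 to 69654474), the serum-responsive cyclin D1, by -0.58 ± 0.09, while CDKN1B, an inhibitor of cyclin-dependent kinases, rose by 0.19 ± 0.05. Of 28 cell cycle inhibitors and quiescence genes 15 rose and 9 fell (median 0.18), with GAS1, PIK3IP1 (1.07 ± 0.10) and TP53INP1 (1.03 ± 0.06) rising and RBL1 (-0.90 ± 0.07) falling.

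Tested against all other genes with a preset correlation of 0.01, the mitosis (camera adjusted p = 4.11e-50), DNA replication (1.15e-35) and histone (4.22e-18) lists were lower and the inhibitor list was higher (0.0177). With an estimated correlation the adjusted p was 0.0849, 0.0849, 0.134 and 0.382, and the inhibitor list was not called by ranks (0.0531). Camera called 19 of 39 lists, 12 higher and 7 lower, and only that of FOXO targets held with an estimated correlation (0.0478). With the donor block as well the lowest adjusted p of any list was 0.163. With TPM scaled to the protein-coding sum the estimated correlation gave 0.0421 for mitosis, DNA replication and FOXO targets and 0.0466 for autophagy and lysosome genes, and no other list was called. Counts of members given here are over all genes tested. The counts adjusted over the list alone were the same for 34 lists and are given for the other 5.

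Of 25 cholesterol synthesis genes 20 rose and 1 fell (22 and 0 with the donor block; median 0.54), among them INSIG1, HMGCS1 (1.25 ± 0.08), the synthase that precedes the rate-limiting step, and LSS (0.95 ± 0.06). Of 18 fatty acid synthesis genes 10 rose and 5 fell (11 and 5 adjusted over the list alone; median 0.23), with SCD (1.34 ± 0.10), the stearoyl-CoA desaturase, FADS2 (1.14 ± 0.09), LPIN1 (0.75 ± 0.06) and FADS1 (0.70 ± 0.07). Of 10 LXR targets 7 rose and 1 fell (7 and 2 with the donor block; median 0.31), with APOE (1.05 ± 0.14), ABCA1 (0.46 ± 0.07), the cholesterol exporter, NR1H3 (0.41 ± 0.05) and APOC1 (0.39 ± 0.05). Camera adjusted p-values were 5.96e-13, 0.00749 and 0.0179, and 0.134, 0.491 and 0.198 with an estimated correlation.

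Of 27 targets of FOXO factors, which are active when insulin and growth factors are scarce, 19 rose and 3 fell (median 0.38), with SOD2, FBXO32, PDK4 (1.08 ± 0.13), the kinase that inhibits pyruvate dehydrogenase, and KLHL24 (1.08 ± 0.07). The list was higher in 94.1% of paired donors, with a camera adjusted p of 7.48e-08 and an adjusted p of 0.0478 with an estimated correlation. With the donor block as well the latter was 0.163. Of 35 autophagy and lysosome genes 25 rose and 2 fell (median 0.20), among them SQSTM1 (1.07 ± 0.08), CTSK (0.86 ± 0.16), NEU1 (0.71 ± 0.08) and CTSF (0.65 ± 0.09). That list had a camera adjusted p of 8.84e-09, and 0.126 with an estimated correlation. Of 27 p53 targets 16 rose and 1 fell (19 and 2 with the donor block; median 0.27, camera adjusted p = 2.23e-06, 0.134 with an estimated correlation), with TP53INP1, BBC3 (0.79 ± 0.07), BTG2 (0.68 ± 0.08) and GDF15 (0.73 ± 0.15). GDF15 was higher in the quiescent library in only 52.9% of paired donors, with means of 48.1 ± 19.01 and 212 ± 468 TPM.

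**Figure D2:**
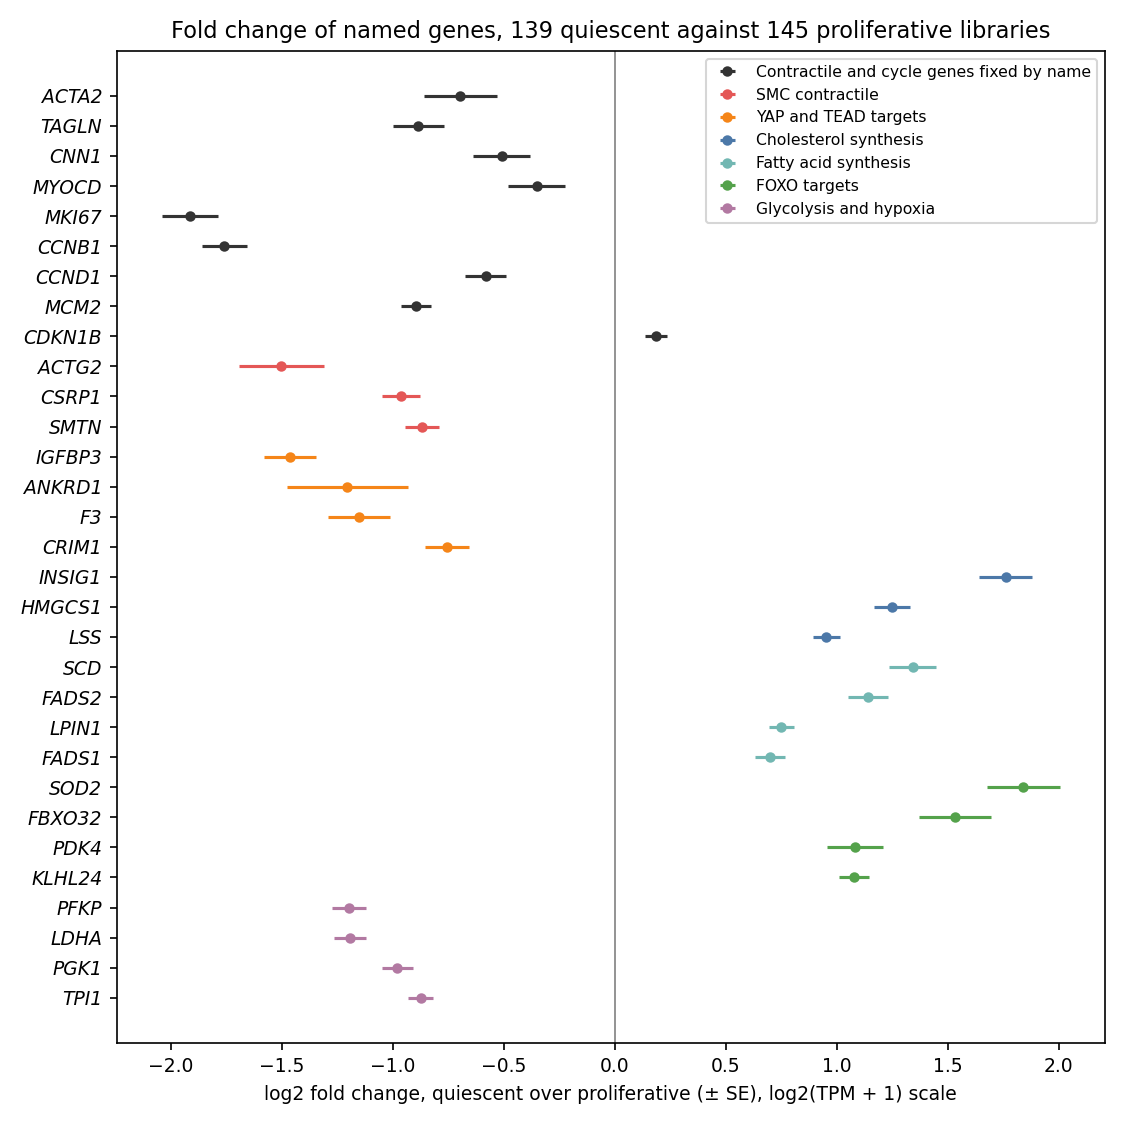
Log2 fold change (quiescent over proliferative, log2(TPM + 1) scale) of genes fixed by name and of list members with the largest changes, as points with bars of 1 SE, over all libraries of both groups. The contractile, YAP and TEAD target and glycolysis genes shown lie left of 0, and the cholesterol, fatty acid and FOXO target genes shown lie right of 0. Members that changed the other way are not shown.

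The contractile genes ACTA2, TAGLN, CNN1 and MYOCD fell without serum. ACTA2 (ENSG00000107796.13, chromosome 10, 88935074 to 88991339), the smooth muscle alpha actin, fell from 219 ± 217 to 157 ± 213 TPM (log2 fold change -0.70 ± 0.16, limma adjusted p = 7.91e-05), in 74.3% of paired donors. TAGLN changed by -0.88 ± 0.12, CNN1 by -0.51 ± 0.13 and MYOCD (ENSG00000141052.17, chromosome 17, 12665890 to 12768949), the coactivator of contractile genes, by -0.35 ± 0.13. MYH11, the smooth muscle myosin heavy chain, was below the filter, at 0.067 ± 0.521 TPM (SD) in proliferative and 0.101 ± 0.545 TPM (SD) in quiescent libraries. Of 28 contractile genes 14 fell, 4 rose and 10 did not pass (median -0.19), with ACTG2 (-1.50 ± 0.19), CSRP1 (-0.96 ± 0.09) and SMTN (-0.87 ± 0.08) falling. Among the 4 that rose, named after their values were seen, were LMOD1 (0.52 ± 0.12), SYNM (0.49 ± 0.09) and SYNPO2 (0.22 ± 0.09). The list was not called by camera (adjusted p = 0.154, 0.727 with an estimated correlation), but was with the donor block (0.0432, 0.570 with an estimated correlation, 7 genes rising and 17 falling) and with TPM scaled to the protein-coding sum (0.0470, 0.674 with an estimated correlation), where its median was -0.08.

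Other lists tied to the smooth muscle state moved in both directions. Of 23 genes of modulated smooth muscle 10 rose and 4 fell (median 0.21), with VCAM1, MGP (0.81 ± 0.20), LUM (0.78 ± 0.18) and DCN (0.65 ± 0.20). Of 41 fibrillar matrix genes 16 rose and 3 fell (22 and 7 with the donor block; median 0.08), with COL14A1, MFAP4 (1.03 ± 0.26), FBLN1 (0.75 ± 0.22) and COL15A1 (0.61 ± 0.22). LUM and DCN of the first list and FBLN1 and MFAP5 of the second are also adventitial fibroblast markers, whose list is given below, and a change of that cell type was not told apart from a change in smooth muscle cells. Camera adjusted p-values were 0.0267 and 0.015, and 0.382 and 0.498 with an estimated correlation. The first was lost with TPM scaled to the protein-coding sum (0.0799). Of 33 matrix proteases and inhibitors 9 rose and 14 fell (median 0.01, mean -0.17, camera direction up, adjusted p = 0.894), with falls of PLAT (-1.57 ± 0.12), the tissue plasminogen activator, TIMP3 (-1.43 ± 0.15) and MMP1 (-1.23 ± 0.27). Of 19 osteochondrogenic genes 5 rose and 5 fell (6 and 2 under each of the 3 scalings; median 0.02, adjusted p = 0.432), with SLC20A1 at -0.88 ± 0.09, BMP4 at 0.72 ± 0.11 and OGN at 0.76 ± 0.32. Of 13 Notch targets 4 rose and 4 fell (7 and 5 with the donor block, 5 and 1 under each of the 3 scalings; median 0.06, mean -0.05, adjusted p = 0.489), with HEY2 at -0.84 ± 0.14, HEY1 at 0.41 ± 0.10, NOTCH1 at 0.38 ± 0.08 and JAG1 at -0.37 ± 0.13. The calls of JAG1 under each of the 3 scalings and of OGN without a filter or with robust regression were lost.

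Targets of serum signalling were also mixed. Of 24 YAP and TEAD targets 14 fell and 5 rose (median -0.22), with IGFBP3 (-1.46 ± 0.12), ANKRD1 (-1.20 ± 0.27), F3 (-1.15 ± 0.14), the tissue factor, and CRIM1 (-0.76 ± 0.10). Camera did not call this list (adjusted p = 0.154, 0.682 with an estimated correlation) except with the donor block (0.0432, 0.510 with an estimated correlation). Of 26 TGF-beta targets 12 fell and 4 rose (15 and 6 with the donor block, 9 and 7 under each of the 3 scalings; median -0.12, adjusted p = 0.555), with IL11 (-1.31 ± 0.13), ID1 (-1.05 ± 0.13) and TGFBI (-0.75 ± 0.11), and their median changed sign to 0.013 with median-ratio and 0.037 with upper quartile factors. Of 33 immediate early genes 15 fell and 9 rose (median -0.17, adjusted p = 0.894), with HBEGF (-1.05 ± 0.17), FOSL1 (-0.87 ± 0.09), DUSP1 (-0.69 ± 0.11) and DUSP6 (-0.58 ± 0.08), while 11 rose and 10 fell with median-ratio factors, 12 and 10 with upper quartile factors and 10 and 12 with the protein-coding sum. The matrix protease counts likewise turned to 14 rising and 11 falling under each of the 3 scalings.

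Inflammatory and interferon genes differed in direction by gene. Of 31 NF-kB genes 16 rose and 7 fell (median 0.22, camera adjusted p = 0.00513, 0.662 with an estimated correlation), with VCAM1, SOD2 and the chemokine CXCL2 (1.44 ± 0.19, in 87.5% of paired donors) rising and IL1B falling. The mean of the list was higher in only 50% of paired donors. Of 35 interferon response genes 22 rose and 4 fell (23 and 4 adjusted over the list alone; median 0.26, camera adjusted p = 2.86e-05, 0.389 with an estimated correlation), with IFIT2 (0.89 ± 0.08), IFIT1 (0.81 ± 0.11), GBP2 (0.80 ± 0.10) and MX1 (0.75 ± 0.13). Of 18 complement genes 11 rose and 3 fell (median 0.24, camera adjusted p = 0.0301, 0.558 with an estimated correlation), with C3 (0.81 ± 0.20), CLU (0.69 ± 0.18), CFB (0.68 ± 0.16) and C1S (0.66 ± 0.13). The complement call was lost with TPM scaled to the protein-coding sum (0.0834), and with median-ratio factors both it (0.0828) and the NF-kB call (0.0585) were lost.

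Of 35 genes of glycolysis and hypoxia 24 fell and 5 rose (median -0.39, camera adjusted p = 3.88e-05, 0.434 with an estimated correlation), with PFKP (-1.20 ± 0.08), LDHA (-1.19 ± 0.07), the lactate dehydrogenase, PGK1 (-0.98 ± 0.07) and TPI1 (-0.87 ± 0.06). Of 41 nuclear genes of oxidative phosphorylation 40 fell and 1 did not pass (median -0.30, camera adjusted p = 6.17e-17, 0.134 with an estimated correlation), with CYCS (-0.84 ± 0.06), ATP5MC1 (-0.83 ± 0.06), NDUFB3 (-0.58 ± 0.06) and ATP5F1B (-0.53 ± 0.04). Of 13 mitochondrially encoded genes 12 fell (13 adjusted over the list alone; median -0.31, adjusted p = 0.0751, 0.0156 by ranks, 0.694 with an estimated correlation; 7 to 8 fell under the 3 scalings), with MT-ND6 (-0.65 ± 0.08) and MT-ND5 (-0.43 ± 0.09), while the mitochondrial ribosomal RNA share of estimated reads was 12.8% ± 1.69 (SD) in proliferative and 14.4% ± 2.30 (SD) in quiescent libraries. Of 40 ribosome biogenesis genes 38 fell (median -0.32, camera adjusted p = 4.76e-11, 0.23 with an estimated correlation), with NHP2 (-0.53 ± 0.03), BOP1 (-0.52 ± 0.05), NOP16 (-0.52 ± 0.05) and PNO1 (-0.51 ± 0.05).

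Of 19 genes for chaperones and stress of the endoplasmic reticulum 16 fell and 1 rose (median -0.40, camera adjusted p = 1.91e-05, 0.23 with an estimated correlation), with SDF2L1 (-0.82 ± 0.06), MANF (-0.80 ± 0.06), CALR (-0.60 ± 0.05) and CRELD2 (-0.58 ± 0.05). Of 31 ATF4 and amino acid genes 20 fell and 6 rose (21 and 6 adjusted over the list alone; median -0.28, adjusted p = 0.154), with STC2 (-1.19 ± 0.11), SLC7A5 (-0.78 ± 0.08) and ASNS (-0.65 ± 0.12) falling. Of 53 ribosomal protein genes 9 rose and 9 fell (7 and 6 adjusted over the list alone, 16 and 13 with the donor block; median 0.01, adjusted p = 0.265), with RPL35 at -0.25 ± 0.03, RPL3 at 0.15 ± 0.04, RPSA at -0.14 ± 0.03 and RPS27 at 0.13 ± 0.05. This family turned with the scaling: 43 rose and 1 fell with TPM scaled to the protein-coding sum (camera adjusted p = 2.24e-04, 0.706 with an estimated correlation), 44 and 1 with median-ratio factors and 50 and 1 with upper quartile factors, and the call of RPSA was lost under each of them.

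Among the remaining lists, 9 of 18 circadian clock genes rose and 2 fell (median 0.13, adjusted p = 0.0791, 0.0237 with the donor block and 0.410 with an estimated correlation as well), with NFIL3 (0.62 ± 0.09), RORA (0.47 ± 0.06), BHLHE41 (0.44 ± 0.09) and CLOCK (-0.46 ± 0.04). Of 19 glucocorticoid targets 7 rose and 7 fell (median 0.08, mean -0.02, adjusted p = 0.432), with PDK4 and NFKBIA (0.82 ± 0.09) rising and MT2A (-1.11 ± 0.13) falling. Of 9 metallothioneins, which are near-identical genes, 5 fell (median -0.11, adjusted p = 0.535), with MT1E at -0.44 ± 0.10. Of 60 genes near coronary artery disease loci 29 rose and 18 fell (30 to 31 and 9 under the 3 scalings; median 0.07, adjusted p = 0.0877, 0.0179 with the donor block and 0.516 with an estimated correlation as well), with PSRC1 (-0.995 ± 0.07), PDGFD (0.87 ± 0.19) and JCAD (0.81 ± 0.12).

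Markers of other cell types were examined as well. Of 12 endothelial markers 1 fell, TEK (-0.77 ± 0.16), and 11 did not pass (median 0.06, adjusted p = 0.555). With the donor block 6 rose and 3 fell. Their mean log2(TPM + 1) was at least 3 in 17 libraries of each group, with medians of 1.64 and 1.57 and maxima of 5.84 and 6.96, and correlated between the libraries of a donor (Pearson r = 0.983, Spearman rho = 0.922, permutation p = 1e-05 each, the smallest they can give, over all paired donors, r = 0.979 without the 2 farthest). Of 15 adventitial fibroblast markers 5 rose and 2 fell (median 0.18, adjusted p = 0.154, 0.00663 with the donor block and 0.203 with an estimated correlation as well, 11 rising and 3 falling with the block), with LUM, FBLN1 and DCN rising and THY1 (-0.47 ± 0.10) falling. Of 9 pericyte markers 1 rose, PDGFRB, and 1 fell, ANPEP (-0.89 ± 0.11; median -0.0028, adjusted p = 0.606), with a median above 0 under each of the 3 scalings. With the donor block 3 rose and 5 fell. Of 6 epithelial and mesothelial markers 1 rose and 4 fell (median -0.63, adjusted p = 0.537), with KRT18 (-0.94 ± 0.15) and KRT8 (-0.66 ± 0.17). Of 5 neural and Schwann cell markers 2 rose and 1 fell (adjusted p = 0.879), with TUBB3 (-0.97 ± 0.07) and PMP22 (0.46 ± 0.07), and of 5 leukocyte markers 1 rose and 2 fell (adjusted p = 0.696), with CD79A (0.11 ± 0.02). Cardiomyocyte markers had 4 tested members and were not tested as a list.

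Other member counts moved by over 1.5 times, or from or to 0, under at least 1 of the 3 scalings, and are given here as rises and then falls over them. Cholesterol synthesis had 24 and 0, fatty acid synthesis 12 to 13 and 3, autophagy and lysosome 32 and 0 to 2, and p53 targets 22 to 25 and 0. Modulated smooth muscle had 11 to 12 and 2, interferon response 26 to 27 and 1 to 3, and circadian clock genes 12 to 13 and 1. Nuclear oxidative phosphorylation had 1 to 4 and 34 to 36, ribosome biogenesis 1 to 2 and 29 to 33, stress of the endoplasmic reticulum 2 to 3 and 12, and metallothioneins 1 and 3 to 4. Glucocorticoid targets, below that limit, went from an even split to 10 and 5 to 6. Markers had 8 and 1 to 2 (adventitial fibroblasts), 0 to 2 and 1 (endothelial), 3 and 1 (pericytes), 2 and 4 (epithelial and mesothelial) and 1 and 1 to 2 (leukocytes).

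The next comparison asked how far differences between donors were shared by both conditions. No donor number had repeated libraries in a condition, so a donor cannot be told apart from its culture. Differences between cultures, as in their mix of cells or handling, would be shared as well if both libraries came from the same culture. Expression was positively correlated between a donor's proliferative and quiescent libraries for 15511 of 21089 genes and negatively for 39 (adjusted p of 0.05 or below, Benjamini-Hochberg), with a median Pearson r of 0.348 over the paired donors. With shuffled donor numbers the median r was 0.00036. Among the highest correlations were those of HLA-C (r = 0.994, rho = 0.983), which presents peptides to T cells, MICA (r = 0.981, rho = 0.970), a stress-induced ligand of natural killer cells, IGFBP2 (r = 0.986, rho = 0.986), CCDC3 (r = 0.984, rho = 0.985), CFI (r = 0.982, rho = 0.982), an inhibitor of complement, MCAM (r = 0.979, rho = 0.968), MOXD1 (r = 0.978, rho = 0.974) and FMOD (r = 0.978, rho = 0.975), a collagen-binding proteoglycan. Each had a permutation p of 1e-05 for both coefficients, the smallest they can give, and an r of at least 0.976 without the 2 farthest donors. After removing 5 components per condition, r was 0.719 for MCAM, 0.862 for IGFBP2, 0.887 for CFI and 0.888 for CCDC3. It was then 0.923 for MOXD1, 0.931 for FMOD, 0.972 for MICA and 0.977 for HLA-C. Reads of HLA-C and MICA map according to how closely a donor's alleles match the reference. GSTM1, a glutathione transferase, was also among the 10 highest, but its values fell into separate clusters with a gap of 55.8% of their range, so no pooled r is given.

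**Figure D3:**
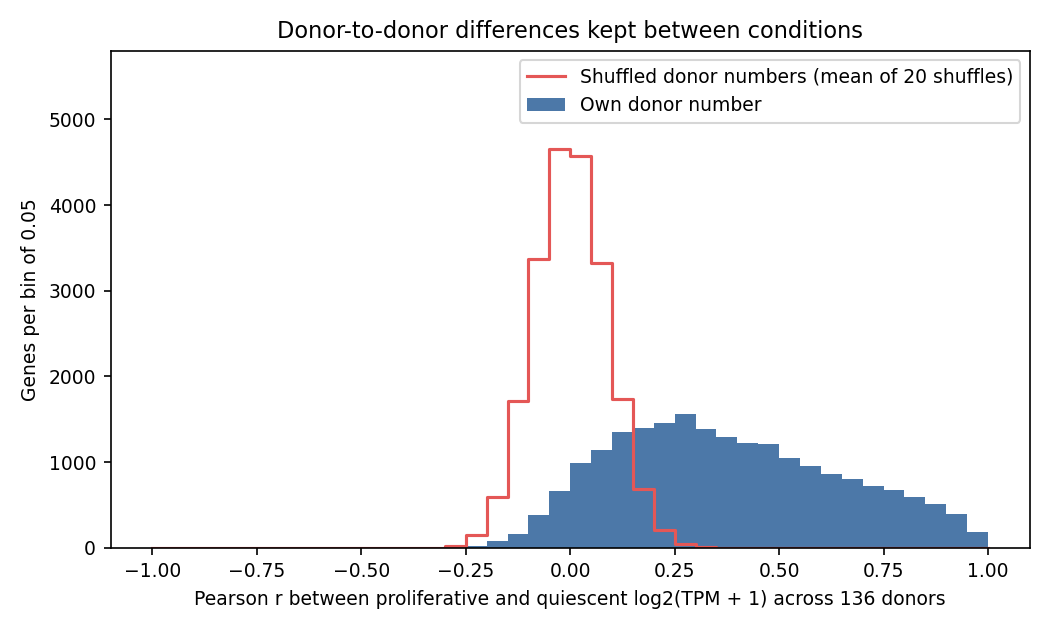
Number of genes per bin of 0.05 of Pearson r between proliferative and quiescent log2(TPM + 1) across the paired donors, with bars for the donors' own numbers and a line for the mean of 20 shuffles. The bars lie to the right of the line, with 6758 genes over an r of 0.5.

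By list, the median r over members was highest for markers of endothelial cells (0.949) and adventitial fibroblasts (0.931), complement (0.886), genes of modulated smooth muscle (0.866) and fibrillar matrix (0.860), and 0.730 for contractile genes. It was lowest for mitochondrially encoded genes (0.160), DNA replication (0.180), cholesterol synthesis (0.212) and nuclear oxidative phosphorylation genes (0.226). These medians are across genes, which are not independent replicates. The mean of the endothelial markers was at least 3 in 17 libraries of each group. Whether these libraries carry the endothelial median was not tested.

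Spread between donors also differed between conditions. Of 21089 genes, 12818 had a wider and 1314 a narrower spread in quiescent cells (Pitman-Morgan test, adjusted p under 0.05). Among genes of division, 42 of 48 mitosis genes, 20 of 27 histone genes and 21 of 40 DNA replication genes (6 wider) were narrower. The mitosis and DNA replication genes fall to a few TPM on average, where the added 1 compresses spread. With a pseudocount of 0.1 their counts were 6 and 9 (11 DNA replication genes wider), while the histone count stayed at 20. The 5 genes with the largest fall in spread, which were narrower with either pseudocount, were KIF22 (SD 0.709 to 0.427 in log2 units), H2AC8 (0.954 to 0.583), PSMC3IP (0.642 to 0.399), MCM7 (0.816 to 0.509) and H2BC11 (1.04 to 0.654). Wider lists were immediate early genes (28 of 33), nuclear oxidative phosphorylation (34 of 41), cholesterol synthesis (20 of 25) and glycolysis and hypoxia (31 of 35), none of which had a narrower member. The single genes with the largest rise in spread were GOLGA1 (0.131 to 0.757), AGGF1 (0.157 to 0.890), SNX17 (0.129 to 0.720), ORC3 (0.174 to 0.964) and KLHL12 (0.147 to 0.802). Their mean lay more than 1 log2 unit below the proliferative mean in 18 quiescent libraries (12.9%) and 0 proliferative ones. After removing 5 components per condition, 7794 genes were wider, and the 5 genes named as narrower were wider. The log2 variance ratios of the 5 genes named as wider dropped from between 4.90 and 5.06 to 1.22 for GOLGA1, 0.71 for AGGF1, 0.93 for SNX17 and 0.75 for ORC3, and to 0.29 for KLHL12, which no longer passed.

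**Figure D4:**
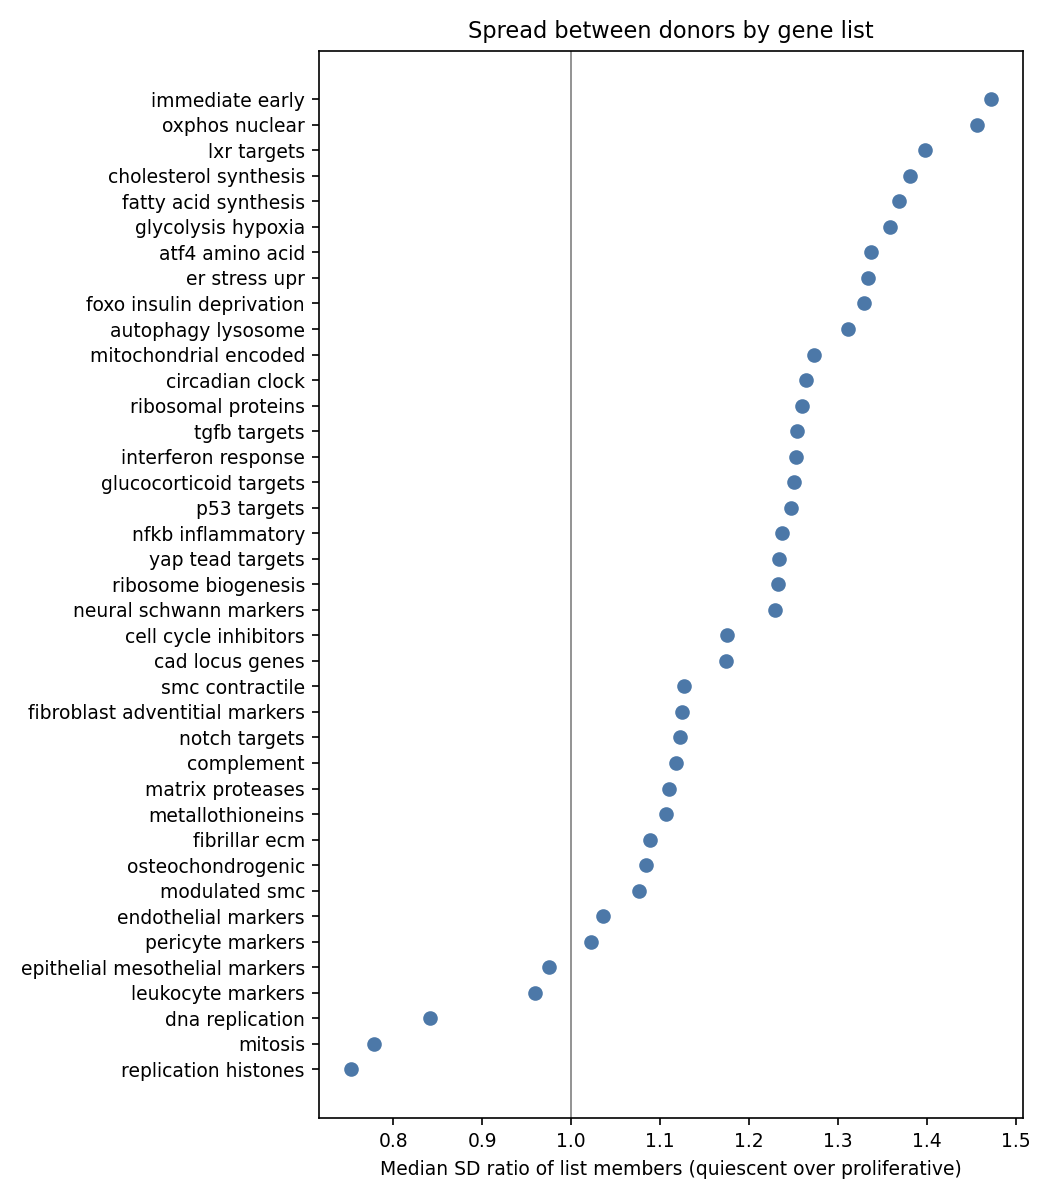
Median ratio of the SD between paired donors, quiescent over proliferative, of the members of each tested gene list (1 point per list). Values under 1, as for replication-dependent histones (0.753) and mitosis (0.779), are narrower spreads without serum. With a pseudocount of 0.1 these were 0.766 and 0.917.

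The last comparison asked whether donors whose cells divide more express less of the contractile genes. In proliferative libraries the mean z score of the mitosis genes and that of the contractile genes had a Pearson r of -0.15 (permutation p = 0.0677, the same when adjusted) and a Spearman rho of -0.16 (p = 0.0593, the same when adjusted). In quiescent libraries r was 0.24 (p = 0.00555, adjusted 0.00833) and rho 0.23 (p = 0.00663, adjusted 0.00995). The changes of both scores correlated across paired donors with an r of 0.33 (p = 0.0002, adjusted 6e-04) and a rho of 0.28 (p = 0.00105, adjusted 0.00315). These are 3 relations of 1 family, adjusted by Benjamini-Hochberg, and without the 2 farthest samples r was -0.22, 0.26 and 0.33. The quiescent relation was lost without the libraries high in endothelial markers (r = 0.16, p = 0.0747), and that in proliferative libraries passed there (r = -0.20, p = 0.024). Whether the relations differ between conditions was not tested.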

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

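The tests of splits with the donor block, of cells of another type and of scaling for single contractile genes were chosen only after the result was seen, as were those of scaling for the spread and of exchanged labels in 3 donors. The other tests here were written beforehand.

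Spike-in sequences were left out of the comparisons as features but were present in every library. Their mean sum was 42096 TPM in proliferative and 39893 TPM in quiescent libraries (SD 23659 and 20365). No library without spike-in served as a control. The sum ranged from 288 to 102869 TPM and from 104.98 to 95398 TPM.

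Of 28 contractile genes 14 fell and 4 rose without serum (median log2 fold change -0.19), and camera did not call the list (adjusted p = 0.154, 0.727 with an estimated correlation). Composition of TPM is argued against for single genes, since 13 of the 14 also fell under each of the 3 scalings, while for the list as a whole a change and a shift of scale cannot be told apart, as the median was -0.063 with median-ratio factors (adjusted p = 0.0553) and -0.08 with the protein-coding sum (0.0470). More cells of another type are not excluded, since the 4 rises could come from a type that expresses these genes, and adventitial fibroblast markers (median 0.18, higher in 82.4% of paired donors, the most abundant being CCDC80 with 509 and 690 TPM) were called higher with the donor block (0.00663, 0.203 with an estimated correlation). A loss of serum-driven YAP and TEAD target expression would tie the changes of the contractile and the YAP and TEAD target scores. These rose together across paired donors (r = 0.636, rho = 0.664, permutation p = 1e-05 each, the smallest they can give, r = 0.61 without the 2 farthest, no shared genes). A shift of a whole library would tie them as well, and the test was not repeated after scaling. The contractile change also rose with that of the mitosis score (r = 0.33), so the relation is not found with these targets alone. It does not single out this cause, nor show which of the scores leads.

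In 5 paired donors the mitosis genes were higher in the quiescent library, by 2.77 and 2.81 log2 units in 2 of them and at most 0.88 in the others. An exchange of condition labels within these 2 donors is a candidate explanation, since over 500 genes outside the cycle lists their changes correlated with the mean change of the other donors at -0.949 or below, against a median of 0.909 in other donors. For incomplete arrest with cycle genes alone out of place a positive correlation was predicted, and the lowest was -0.958. Genes tied to division but outside the cycle lists may be among the 500, so this correlation alone does not exclude incomplete arrest. Incomplete arrest would leave the mitosis genes of the quiescent library at most as high as those of its partner. The differences of 2.77 and 2.81 therefore argue against it as the sole cause in these 2 donors. Whether their proliferative cultures divided little was not tested. For the other 3 donors as a set an exchange and a weak response cannot be told apart, since the correlations ran from -0.829, near those of the 2 donors, to -0.19, and 1 further donor, with lower mitosis genes in the quiescent library, was below 0 as well.

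Spread between donors was wider without serum for 12818 genes. If composition of TPM were the source, scaling would remove most of this, yet after scaling to the protein-coding sum 13693 genes were wider. Median-ratio and upper quartile factors were not applied to the spread, so shifts of composition within coding RNA are not excluded. After removing 5 components per condition 7794 genes were wider, so part of the pattern was common to many genes. Depth would go with the first component of the wider genes, which held 39.1% of their variance, yet its rho with estimated reads across quiescent libraries was 0.147 (permutation p = 0.0837; r = 0.121, p = 0.155). The 18 quiescent libraries with low GOLGA1, AGGF1, SNX17, ORC3 and KLHL12 (down to -3.39 log2 units from the proliferative mean, with pairwise correlations of the genes of at least 0.942) are part of this spread. Differences in how cells of different donors respond stay open, as untested, and so do differences in handling.

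The counts of changed genes were set against 100 splits of the libraries, of which 50 others parted the paired donors as the real one does and 49 did not. The real split gave 13384 genes past the threshold and 330 with at least a 2-fold change, and the highest of the other splits was 0 for both, so that only 1 of the 100 splits, the real one, was as large. Differences between donors stay in the residual there and hold such counts low. With the donor block, the conditions were exchanged within random paired donors in 99 other splits of 100. The real split gave 15212 and 328 genes and the highest other 0 for both, so that only the real one of the 100 was as large. The exchanged changes stay in the residual there too and hold such counts low. A count of 0 therefore does not exclude chance for single calls, nor measure how many calls are false.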

How the results depend on the processing

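Choices made before the data were examined are those of the planned settings, and the scaling to the protein-coding sum, the residual components, the pseudocount for the spread, robust regression and the fits without donors in doubt or without endothelial-high libraries were chosen after seeing the data. Count-based alternatives planned for the comparison were not run because the values are TPM, library totals are identical to the TPM as deposited, and no library had a total under 50% of the median. The count of 13384 genes moved to 8902 with at least 1 TPM in at least 50% of libraries, which tests fewer genes, and stayed within 1.5 times under the other settings that test for any change (10638 to 15212), while a test against a 1.5-fold change gave 489. The count of 330 genes with at least a 2-fold change moved to 620 with a pseudocount of 0.1, as a smaller pseudocount enlarges changes of low genes, and was otherwise 280 to 378. With the donor number as a block it was 328, with 322 of the same genes, and 15212 genes passed in all. The block raised the lists called by camera from 19 to 24, adding those named in the report, and none of the 19 was lost. It also moved counts of list members by over 1.5 times in some lists, for which the report gives both, and genes named only for their donor correlation, such as HLA-C, IGFBP2 and MCAM, passed with it and not without. With an estimated correlation camera called 1 list, and with the block as well the lowest adjusted p was 0.163, while with scaling to the protein-coding sum it also called mitosis and DNA replication (0.0421) and autophagy and lysosome genes (0.0466). Leaving out the donors in doubt gave 378 genes, all 330 among them.

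Genes correlated between conditions went from 15511 to 7730 where only genes with a mean log2(TPM + 1) of at least 2 were tested, which leaves 9979. Wider genes went from 12818 to 7794 after removing 5 components, narrower genes from 1314 to 614 with a pseudocount of 0.1, and the log2 variance ratios of the narrower genes reversed to 2.35 for KIF22, 2.04 for H2AC8, 1.21 for PSMC3IP, 1.43 for MCM7 and 2.40 for H2BC11. RPSA reversed to 0.024 with upper quartile factors, an effect of the change of scale. In proliferative libraries the correlation of the division and contractile scores passed with the DNA replication list (-0.23), with scaling to the protein-coding sum (-0.19), without donors in doubt (-0.1995) and without endothelial-high libraries (-0.1994), and in quiescent libraries it no longer passed without the latter (0.16). The cause was not tested. Of 2175 fold changes of named genes under the alternatives, 2142 kept their side of the threshold, 32 lost it and 1 reversed. Of 80 values of genes named for donors, 5 reversed, 1 lost the call and 74 did neither. Correlations among the 80 were judged by sign alone and could not lose a call. That of MCAM, 0.719 after removing 5 components per condition, is thus among the 74. Of 234 camera results, 205 kept their side, 8 gained and 21 lost the call. Depth is known only as an estimate, so no counting limit is given for single genes.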

Other observations

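Differences between donor numbers, where donor and culture cannot be told apart, were also shared by both conditions in gene groups not described above. The median r over members between a donor's proliferative and quiescent values was 0.809 for osteochondrogenic genes, 0.773 for Notch targets, 0.755 for NF-kB inflammatory genes and 0.701 for ribosomal proteins, against 0.298 for mitosis genes. Ribosomal protein genes were wider between donors without serum in 45 of 53 cases, autophagy and lysosome genes in 27 of 35 and FOXO targets in 20 of 27 (1 narrower), and 5 of 12 endothelial markers were wider and 1 narrower.

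A donor's libraries in both conditions were closest to each other more often than to those of other donors. Over the 1000 most variable genes the quiescent library of the same number was the closest one for 91.9% of proliferative libraries, and the proliferative one for 95.6% of quiescent libraries. Over all tested genes it was 85.3% and 86.8%. In 1 donor the libraries were nearly identical (r = 0.997, next highest 0.993), and were counted as separate, as in the labels. Whether they come from separate samples is not known. They differed by more than counting noise on estimated reads (median chi-square index 4.08), but so would 2 preparations of 1 RNA sample.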
